A study of Homo sapiens with 20 samples.

How the data were processed

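DNA methylation was measured in 20 human samples. They were 7 benign prostate tissues, 7 localized prostate cancers and 6 metastatic castration-resistant prostate cancers (CRPC), with the groups taken from the labels. Per the labels' protocols, the assay was enhanced reduced representation bisulfite sequencing: genomic DNA was digested with MspI, an enzyme that cuts at CCGG whether or not the inner cytosine is methylated. Fragments of 150 to 400 bp were then selected, treated with bisulfite, amplified over 18 PCR cycles and read as single ends of 50 bp, per the labels' protocols. Bisulfite turns unmethylated cytosine into a base read as T and leaves methylated cytosine as C, so the share of C at a cytosine is its methylation level. Per the submitters' processing notes, the aligner was Bismark, with a version not given in the sources used here, and both builds hg18 and hg19 are named. The listed positions fit the chromosome lengths of hg19 and not those of hg18, so all coordinates are given on hg19, counted from 1.

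The deposited files hold, for each cytosine, the count of reads calling C and the count of reads calling T, not normalized, as whole numbers. Only cytosines with at least 10 reads are listed in them, a minimum tested on the files, and they carry no strand. Trimming, handling of duplicate reads and the other settings behind these counts are not given in the sources used here. Everything below was computed from these counts. The files held between 165402316 and 180753533 C or T calls in each benign sample, between 137600869 and 173626340 in each localized cancer and between 89623052 and 169308102 in each CRPC sample. Median coverage of a listed site ran from 19 reads in CRPC sample 4 to 54 reads in the benign group. A level of 50.0% has a 95% Wilson interval of 23.7% to 76.3% at 10 reads and of 37.1% to 62.9% at 54 reads, and 9 methylated of 19 reads (47.4%) have one of 27.3% to 68.3%. Reads of a PCR library without molecular identifiers are not independent molecules, so these intervals cover counting error only. Cytosines of mitochondrial DNA, which is taken here as nearly unmethylated, were called methylated in 0.056% to 0.251% of reads, a bound on failed bisulfite conversion.

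Chromosomes 1 to 22 and X were analysed. Single cytosines (sites) were tested where at least 5 samples of each group listed them. A quasi-binomial logistic model was fitted to the counts of each site, its dispersion was held at 1 or above and moderated across sites with squeezeVar of limma 3.58.1 in R 4.3.3, and the groups were compared with a two-sided F test and Benjamini-Hochberg adjustment. Regions were non-overlapping tiles of 1 kb with at least 3 sites listed in all 20 samples. Reads were summed per tile, and limma was run on log2 of methylated over unmethylated reads with a pseudocount of 1 added to each, with Benjamini-Hochberg adjustment over the tiles. A site or tile was called changed at an adjusted p below 0.05 together with a difference of the group means of at least 20 percentage points (points below). Levels are given in percent, and a tile's level is its methylated reads over all its reads. Each comparison used only its own 2 groups. P-values measure the spread between the tissues of a group, which the labels describe as separate samples.

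For each sample, the mean level was taken over the 1303567 autosomal sites listed in all 20 samples, and again in classes of local density, counted as the number of such sites within 100 bp. This is a density of measured sites, which also depends on the MspI fragments and the coverage, and not the density of CpG in the genome. Sparse sites had at most 3 neighbours, intermediate sites at most 10 and dense sites more. The spread of a sample was its mean absolute difference in level from the other samples of its group. Both were compared with a two-sided exact permutation test, whose smallest possible p with all samples is 0.000583 in every comparison. Benjamini-Hochberg adjustment was over 12 tests of mean levels and 3 tests of spread. The spread values of a group share pairs of samples and so are not fully independent. They were computed within the real groups and not again for each permutation. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 was used for these steps.

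Tests, thresholds, groups, density classes, the alternatives and the rule for named regions were fixed before the data were examined. That rule takes, for each comparison, the 10 called tiles with the largest rise and the 5 with the largest fall among those whose samples do not overlap between the groups. Promoter windows and gene lists had been planned for the case that an annotation of hg19 was at hand. The gene table used here is on another build, so promoters, gene lists and gene names were not analysed here and regions are given by position. Further summaries were chosen after the data were seen: windows of 500 kb with at least 10 tiles, tiles that set benign samples 4 and 5 apart from the others, the fate in CRPC of the tiles called in localized cancer, and each count without samples that stood apart.

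Benign and localized samples carry the same numbers 1 to 7 in the labels. At 29610 candidate variant sites, with every sample within 15 points of 0%, 50% or 100% and a range of at least 35 points, deviations from the group mean were correlated between benign and localized samples. Samples of the same number correlated at 0.119 to 0.314 and those of different numbers at 0.013 at most. Each of the 7 numbers matched its own best in both directions, so these numbers were taken to pair the samples, a pairing the labels give only as numbers. A fit with the replicate number as a block was run as an alternative.

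The tests were first tried on simulated data drawn from the real coverages and levels. Every simulated sample had the same dispersion, so groups that differ in spread, as the real ones do, were not simulated. Only rises were simulated, and recovery was counted on the adjusted p alone. Among 60000 simulated sites, the quasi-binomial model recovered 78.0%, 73.0% and 60.0% of sites changed by 35 points, for localized against benign, CRPC against localized and CRPC against benign, and 23.0%, 20.0% and 7.0% of those changed by 20 points. It made 0, 2 and 1 false calls of 20 points or more, and 7.49%, 7.50% and 7.27% of unchanged sites had an unadjusted p below 0.05, somewhat more than the nominal share. With the replicate block there were 9, 9 and 4 such false calls. Among 30000 simulated tiles, limma recovered 68%, 54% and 70% of those changed by 35 points and 5%, 5% and 6% of those changed by 20 points, with 0 false calls of 20 points or more by limma in each comparison. Most changes near 20 points were therefore missed in simulated data. Only 100 sites or tiles of each size were changed there, a smaller share than was called against benign tissue. Benjamini-Hochberg adjustment is stricter when fewer are changed, so these shares need not hold for the real data.

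The alternatives were a coverage minimum of 20 or 30, a difference of 10 or 30 points, limma on single sites, summing both strands of a CpG, one dispersion from all 3 groups, leaving out the most deeply covered sites or chromosome X, the replicate block, pseudocounts of 0.1 and 5, the quasi-binomial model or unweighted mean levels for tiles, at least 10 sites per tile, and tiles of 500 bp. For mean levels and spread they were coverage weighting, all sites of each sample, chromosome X added, reads thinned to 10 per site, candidate variant sites left out, and 1 minus Pearson's correlation in place of the mean difference.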

Results

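The series set out to compare DNA methylation between benign prostate tissue, localized prostate cancer and metastatic castration-resistant prostate cancer, a form that progresses despite androgen deprivation. The groups held 7 benign, 7 localized and 6 metastatic samples, read to between 89623052 and 180753533 calls each. The files listed between 2581617 and 3450658 cytosines per sample at 10 reads or more. Median coverage was 47 to 54 reads in benign, 40 to 49 in localized and 19 to 46 in metastatic samples. Of 5416967 sites listed in at least 1 sample, 1318325 were listed in all 20. Because MspI fragments come mostly from regions rich in CpG, the measured sites over-represent such regions.

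Methylation at sites with many measured neighbours, called dense here, was higher in localized cancer than in benign tissue and higher again in CRPC. Dense sites had a mean level of 5.99% ± 0.17 (SD, n = 7) in benign samples, 7.7% ± 0.79 (SD, n = 7) in localized cancers and 11.2% ± 1.74 (SD, n = 6) in CRPC. All 7 localized samples lay above all benign samples, and all 6 CRPC samples lay above all localized samples. The differences were 1.7 points for localized against benign, 3.45 for CRPC against localized and 5.16 for CRPC against benign. Each gave p = 0.000583 in an exact permutation test, the smallest possible, and an adjusted p of 0.00233. That test ignores the pairing of localized and benign samples by number. With it, an exact sign-flip test of the first difference gave p = 0.0156, the smallest possible with 7 pairs. At a coverage minimum of 20, the first difference was 1.09 points (exact permutation p = 0.000583). Without benign samples 1, 2, 3, 6 and 7, which stood apart from benign samples 4 and 5, the difference of localized cancer from benign was 1.52 points (exact permutation p = 0.0556) and that of CRPC 4.97 points (exact permutation p = 0.0357). At sites of intermediate density, CRPC stood at 41.8% ± 4.13 (SD, n = 6) against 37.2% ± 0.24 (SD, n = 7) in benign samples, a difference of 4.54 points that was shown by 5 of 6 CRPC samples (exact permutation p = 0.00466, adjusted p = 0.014). It was 3.35 points at a coverage minimum of 20 (exact permutation p = 0.0513) and 4.81 points without the same 5 benign samples (exact permutation p = 0.214). Against localized cancer at 37.7% ± 2.19 (SD, n = 7), the difference of 4.09 points had an exact permutation p of 0.0484 and did not hold after adjustment (adjusted p = 0.116), and without localized sample 5 the unadjusted p was 0.0714 in the exact permutation test.

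Sparse sites showed no difference of group means that passed the exact test, but they varied widely among cancers. Their mean level was 72.7% ± 1.03 (SD, n = 7) in benign samples, 68.6% ± 5.56 (SD, n = 7) in localized cancers and 68.7% ± 6.23 (SD, n = 6) in CRPC. Localized samples 4, 6 and 7 and CRPC samples 1, 2 and 4 lay below every benign sample, at 67.6% or less, while CRPC sample 5 at 75.4% lay above them all. The exact permutation p was 0.0967 for localized against benign (0.0449 without localized sample 5), 0.142 for CRPC against benign and 0.959 between the cancers. Over all sites the means were 39.3%, 38.6% and 41.1%, with exact permutation p values of 0.472 for localized against benign, 0.191 for CRPC against localized and 0.237 for CRPC against benign. These depended on the sites taken. Over all sites of each sample CRPC exceeded benign tissue by 4.97 points (exact permutation p = 0.0035) and localized cancer exceeded it by 1.68 (exact permutation p = 0.241). Weighted by coverage, CRPC exceeded benign tissue by 3.43 points (exact permutation p = 0.0204) and it exceeded localized cancer by 3.56 (exact permutation p = 0.0303).

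**Figure D1:**
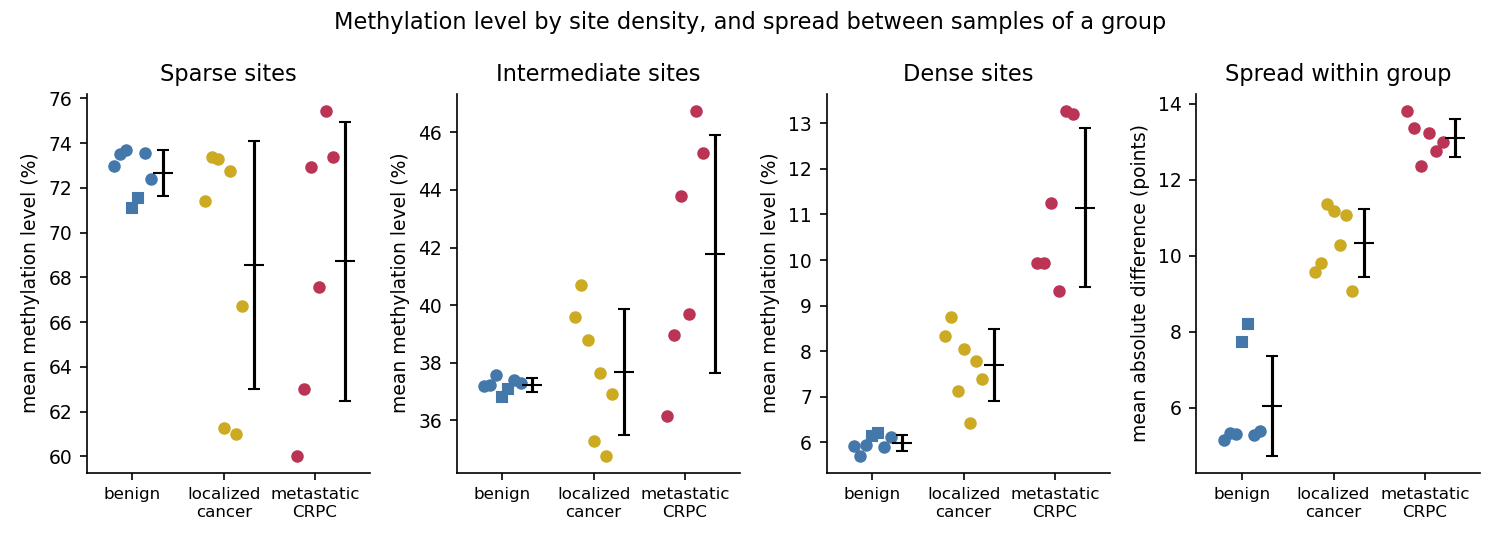
Mean methylation level in percent of each sample at sparse, intermediate and dense sites, and each sample's mean absolute difference in points from the other samples of its group. Points are samples (squares are benign samples 4 and 5), and bars are group means with SD; at dense sites the benign samples lie between 5.71% and 6.22%, the localized cancers between 6.42% and 8.76% and the CRPC samples between 9.31% and 13.3%.

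Tissues of one group differed more among themselves in cancer than in benign tissue, and most in CRPC. The mean absolute difference between samples of a group was 6.05 points ± 1.32 (SD, n = 7) in benign tissue, 10.3 ± 0.89 (SD, n = 7) in localized cancer and 13.1 ± 0.5 (SD, n = 6) in CRPC. The differences were 4.28 points for localized against benign, 2.76 for CRPC against localized and 7.04 for CRPC against benign. Each had p = 0.000583 in an exact permutation test, the smallest possible, also after adjustment, with no overlap of samples. The values of a group share pairs of samples and were not computed again for each permutation. The p values of the spread may therefore be too small. Paired by number, localized against benign had p = 0.0156 in an exact sign-flip test, the smallest possible with 7 pairs. The benign value takes in differences between benign samples 4 and 5 and the other 5. Without benign samples 4 and 5 the difference was 6.69 points for localized cancer (exact permutation p = 0.00126) and 9.45 for CRPC (exact permutation p = 0.00216). Without the other 5 it was 5.42 and 8.18 points. Benign samples 4 and 5 then share their only pair, so both have the same spread and no p is given. Pearson's correlation of site levels, taken across 1303567 sites that are not independent replicates, ran from 0.822 to 0.945 between localized samples and from 0.815 to 0.875 between CRPC samples.

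The benign samples fell into sets of 5 and 2, which are defined from the data and not from the labels. Benign samples 1, 2, 3, 6 and 7 correlated with each other across sites at 0.984 to 0.988, and benign samples 4 and 5 correlated at 0.975 with each other but only at 0.902 to 0.92 with those 5. Localized sample 5 resembled benign samples 4 and 5 more than any cancer, with correlations of 0.965 and 0.97. Between the sets 4900 tiles differed by 40 points or more in every pair of samples, of which 1700 were higher and 3200 lower in benign samples 4 and 5. The tile at chromosome 3, 67706001 to 67707000, stood at 76.2% and 90.5% in benign samples 4 and 5, at 0.3% or less in the other 5, at 83.4% ± 6.8 (SD, n = 7) in localized cancer and at 93.0% ± 6.1 (SD, n = 6) in CRPC. At chromosome 19, 15568001 to 15569000, a tile of 46 sites stood at 8.8% and 1.8% in benign samples 4 and 5, at 96.1% to 97.7% in the other 5, at 6.1% ± 2.6 (SD, n = 7) in localized cancer and at 8.1% ± 7.0 (SD, n = 6) in CRPC. Mitochondrial calls went with the sets. Scaled to a common total of calls they stood at 146.6 to 569.8 RPM in benign samples 1, 2, 3, 6 and 7 and at 2230.8 and 3337.3 RPM in benign samples 4 and 5, against 1013.1 to 3855.0 RPM in localized cancers. The labels call all 7 samples benign prostate tissue, but it was not settled here whether both sets hold the same kinds of cells, so differences from benign tissue are not separated from a difference in cell makeup. The counts of called sites and tiles against benign tissue are therefore also given without each set, while counts in windows, without overlap or shared between comparisons are given with all 7 benign samples only.

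**Figure D2:**
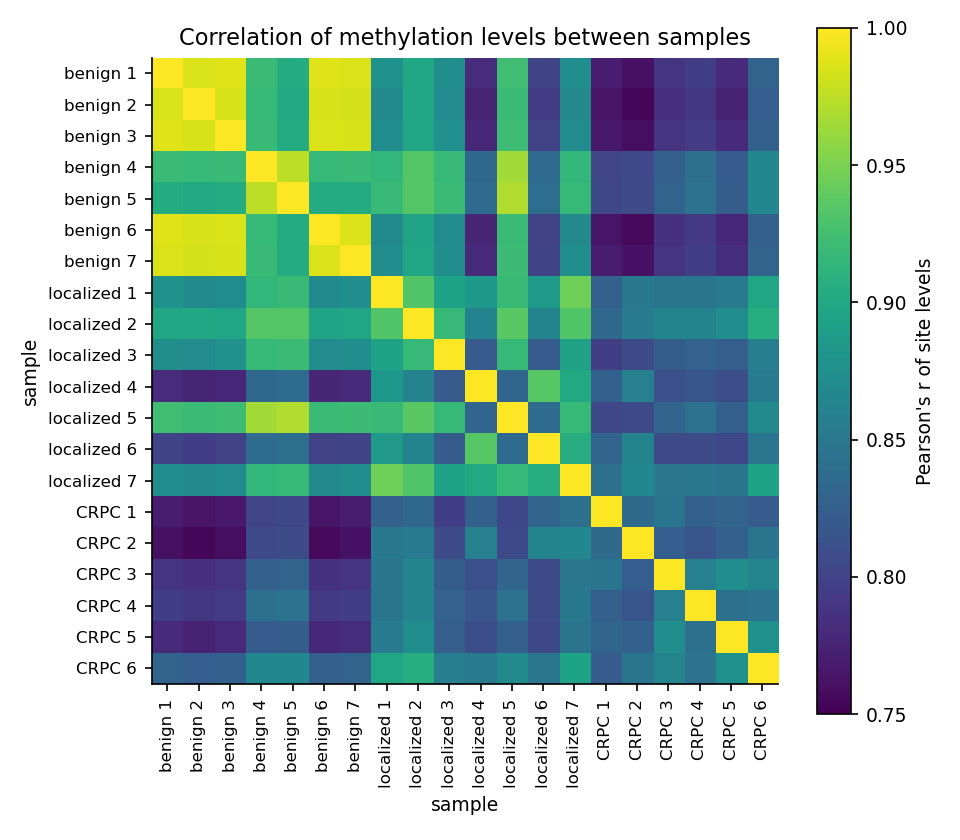
Pearson's correlation of site methylation levels between all pairs of the 20 samples, with samples by group and number on both axes. Benign samples 1, 2, 3, 6 and 7 form a block at 0.984 or above, benign samples 4 and 5 and localized sample 5 a further one at 0.965 or above, and pairs of CRPC samples lie between 0.815 and 0.875.

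Comparing localized cancer with benign tissue asks which methylation changes are present before metastasis. Against all 7 benign samples, localized cancer was higher in many tiles of windows on chromosomes 1, 2, 7 and 12, and lower in windows on chromosomes 1, 20 and 22. These differences are not separated from the parting of the benign samples. In the 500 kb window at chromosome 12, 54000001 to 54500000, 29 of 80 tiles rose, and the window mean went from 17.9% ± 6.3 (SD, n = 7) in benign to 34.8% ± 4.7 (SD, n = 7) in localized samples. In the adjoining windows of chromosome 2 from 176500001 to 177500000, 19 of 37 and 18 of 29 tiles rose, with means going from 16.7% to 39.1% and from 23.4% to 50.0%. Benign samples 4 and 5 were already higher than the other 5 in these windows. They lay at 27.5% and 26.8% against 13.4% to 15.3% on chromosome 12, and at 33.9% and 36.3% against 8.0% to 9.9% in the first window of chromosome 2. In the latter they were close to the localized mean of 39.1%. At chromosome 1, 119500001 to 120000000, 15 of 23 tiles rose, from 34.5% ± 2.9 (SD, n = 7) to 58.2% ± 10.7 (SD, n = 7), with benign samples 4 and 5 at 38.9% and 38.5%. Among windows with many losses was chromosome 1, 2500001 to 3000000, where 64 of 162 tiles fell and the mean went from 70.3% ± 3.7 (SD, n = 7) to 47.9% ± 20.1 (SD, n = 7). At chromosome 20, 60000001 to 60500000, 46 of 122 tiles fell and the mean went from 82.6% ± 3.4 (SD, n = 7) to 52.8% ± 27.6 (SD, n = 7). Benign samples 4 and 5 lay at 64.7% and 65.3% in the former and at 79.4% and 77.0% in the latter. Across the genome 5.4% of tiles rose and 5.7% fell, and the windows were picked for their counts after the data were seen.

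The largest rise among tiles without overlap was at chromosome 5, 176858001 to 176859000, with 12 sites. It went from 10.3% ± 20.2 (SD, n = 7) in benign to 77.9% ± 9.8 (SD, n = 7) in localized samples. Benign samples 4 and 5 stood there at 18.1% and 53.5%. Adjoining tiles at chromosome 7 from 27197001 to 27199000 rose from 15.1% ± 15 to 80.8% ± 10.4 and from 13.5% ± 9.0 to 79.7% ± 12 (SD, n = 7 and 7). Benign samples 4 and 5 stood at 34.2% and 39.4% in the former and at 24.5% and 27.4% in the latter. Chromosome 10 held a tile, 8098001 to 8099000, that rose from 4.7% ± 2.5 to 65.1% ± 22.2 (SD, n = 7 and 7). There benign samples 4 and 5 at 6.7% and 8.0% lay close to the other 5, at 1.5% to 7.0%. The tiles at chromosome 17, 40822001 to 40823000, and chromosome 19, 42703001 to 42704000, rose by 65.2 and 60.3 points, and the tile at chromosome 8, 126503001 to 126504000, rose by 59.1 points from 28.1% ± 5.0 (SD, n = 7). The other 3 named rises, at chromosome 2 from 129037001, chromosome 16 from 11748001 and chromosome 1 from 204164001, were of 60.3, 60.3 and 59.7 points, and benign samples 4 and 5 already stood at 74.3% and 79.3% at the first of these and at 33.3% and 45.9% at the third, which rose by 34.7 points without the other 5. Limma with Benjamini-Hochberg adjustment gave these 10 tiles adjusted p values between 0.000537 and 0.00413. The last 3 tiles held 3 sites each and the tile of chromosome 8 held 4. As the files carry no strand, both strands of a CpG may count as separate sites.

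Among the losses, the tile at chromosome 16, 28549001 to 28550000, fell from 84.3% ± 3.0 (SD, n = 7) to 18.7% ± 14.3 (SD, n = 7), with benign samples 4 and 5 at 89.9% and 83.0%. At chromosome 2, 237278001 to 237279000, a tile fell from 80.2% ± 13.5 (SD, n = 7) to 12.4% ± 15.2 (SD, n = 7), with 74.5% and 53.6% in benign samples 4 and 5. The tiles at chromosome 15 from 89175001 and chromosome 8 from 145237001 fell by 68.1 and 65.5 points, and benign samples 4 and 5 stood between 63.5% and 66.7% there. The tile at chromosome 16, 74778001 to 74779000, fell from 71.9% ± 34 (SD, n = 7) to 6.3% ± 6.3 (SD, n = 7), but benign samples 4 and 5 were already at 19% and 25.5%. Adjusted p values of these 5 tiles by limma lay between 0.00061 and 0.00262. They held only 3 to 5 sites each.

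In counts, 6187 of 115491 tiles rose and 6537 fell (limma, adjusted p below the threshold and 20 points or more). The tiles held a median of 5 sites and 387 reads per sample. Of all 115491 tiles, 2627 had no overlap between the samples of the groups, which chance gives for 0.0583% of tiles, and 1045 rising and 721 falling called tiles were among these. Of 2550581 sites, 124706 rose, by a median of 37.2 points, and 102611 fell, with a median change of -37.3 points. Limma on the same sites called 112536 rises and 63169 falls, so rises made up 64% of its calls. Of the sites tested, 3.35% of dense, 6.24% of intermediate and 4.82% of sparse ones rose, and 0.45%, 2.99% and 6.13% fell. Dense sites, at a mean of 5.99% in benign samples, left little room for falls of 20 points. In tiles with at least 10 sites, 2172 rose and 1023 fell, so the balance moved from 48.6% to 68% of rises. The starting levels of these tiles were not compared with those of the others. The counts moved with the benign samples used. Without benign samples 4 and 5, 282085 sites and 17427 tiles were called. Without the other 5, leaving 2 benign samples, the quasi-binomial model called 0 of 2233591 sites and limma 0 of 115491 tiles. At an unadjusted p below 0.05 and 20 points, 120378 sites (5.39%) and 4988 tiles (4.32%) passed there, and the other tools called 0 sites (limma) and 6 tiles (quasi-binomial). Measured against both benign sets separately, 1924 of the rising and 3278 of the falling tiles differed by 20 points or more from each set. With the replicate number as a block, which pairs the donors, 369212 of 1936347 sites were called in place of 227317 of 2550581, and rises made up 46.0% of them in place of 54.9%. Tiles called with the block numbered 11555.

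**Figure D3:**
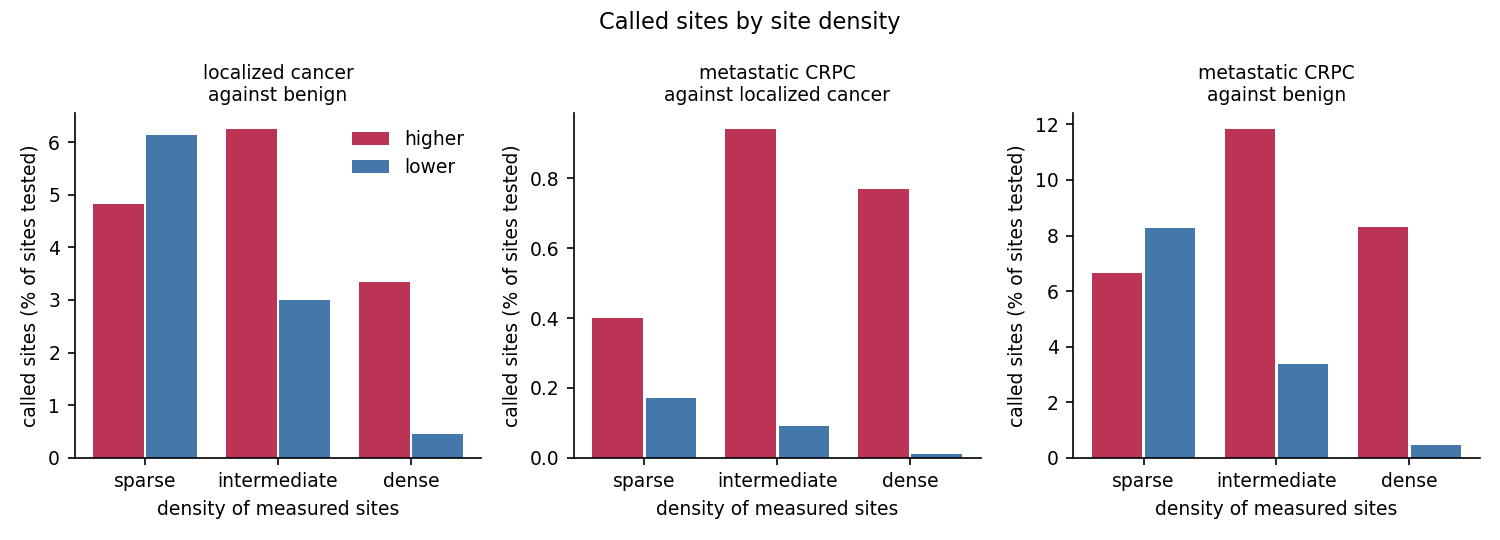
Called sites in percent of the sites tested in each class of local site density, higher and lower separately, for the 3 comparisons; the vertical axes start at 0 and differ in range. Falling sites are most frequent among sparse sites and reach 0.47% of dense sites at most.

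Comparing CRPC with localized cancer asks what differs in castration-resistant disease beyond the primary tumour. Tissue sites and cell mixes of the metastases were not tested, so the differences of CRPC from the other groups are not separated from these. The change was mostly gain, with 824 tiles that rose and 123 that fell. In sites, 14834 rose, by a median of 50.4 points, and 2646 fell, with a median change of -46.8 points. Gains included the window at chromosome 5, 140500001 to 141000000, where 17 of 83 tiles rose and the window mean went from 47.4% ± 9.6 (SD, n = 7) in localized cancer to 75.4% ± 9.2 (SD, n = 6) in CRPC, with benign samples at 38.9% ± 3.0 (SD, n = 7). At chromosome 1, 50500001 to 51000000, 8 of 18 tiles rose, from a mean of 34.1% ± 5.4 (SD, n = 7) to 60.9% ± 8.3 (SD, n = 6). Of the 824 rising tiles, 397 (48.2%) were below 20% in all 7 benign samples, a share that was not set against that of all tiles. Of the 824, 689 were also called higher in CRPC than in benign tissue, in a test that shares the CRPC samples.

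The largest rise among tiles without overlap of CRPC and localized samples was at chromosome 1, 26735001 to 26736000, which was at 1.3% ± 0.6 (SD, n = 7) in benign and 2.0% ± 2.9 (SD, n = 7) in localized samples and at 79.5% ± 16.4 (SD, n = 6) in CRPC. A tile of 47 sites at chromosome 16, 750001 to 751000, rose from 10.4% ± 7.5 (SD, n = 7) to 79.3% ± 14.1 (SD, n = 6), and benign samples stood at 11.3% ± 1.8 (SD, n = 7). Adjoining tiles at chromosome 9 from 706001 to 708000 rose by 65.6 and 67.3 points, from 0.4% and 1.7% in benign tissue and 12.8% and 9.5% in localized cancer. The tiles at chromosome 12, 115129001 to 115130000, chromosome 5, 6687001 to 6688000, chromosome 7, 27233001 to 27234000, and chromosome 19, 17791001 to 17792000, rose by 67.9, 67.5, 67.3 and 65.9 points from localized levels of 13% or less. The tile at chromosome 1, 119535001 to 119536000, went from 5.4% ± 3.8 (SD, n = 7) in benign through 27.8% ± 16.9 (SD, n = 7) in localized samples to 92.8% ± 4.9 (SD, n = 6) in CRPC. The tile at chromosome 17, 79039001 to 79040000, was low in localized cancer alone on the group means, at 17.7% ± 7.1 (SD, n = 7) against 83.0% ± 12.3 (SD, n = 6) in CRPC, but benign samples 4 and 5 stood at 24.6% and 23.3% and the other 5 at 87.4% to 96.4%. Limma with Benjamini-Hochberg adjustment gave these 10 tiles adjusted p values between 0.00532 and 0.0272. At a pseudocount of 0.1 both calls on chromosome 9 ended, with adjusted p values of 0.0786 and 0.0815 by limma. The tiles of chromosomes 1, 5, 7 and 17 held 4 sites each, and that at chromosome 9 from 706001 held 3.

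The 5 named falls were at chromosome 15, 97327001 to 97328000, chromosome 12, 98911001 to 98912000, chromosome 14, 93483001 to 93484000, chromosome 8, 1244001 to 1245000, and chromosome X, 16801001 to 16802000. The first fell from 83.8% ± 17.6 (SD, n = 7) to 18.7% ± 11.7 (SD, n = 6), with benign samples at 78.2% ± 4.0 (SD, n = 7), and the last from 93.7% ± 5.9 (SD, n = 7) to 33.3% ± 26.4 (SD, n = 6). At the tile of chromosome 8 benign samples 4 and 5 were at 47.7% and 12.7%, and the other 5 at 91.9% to 95.5%. Adjusted p values by limma lay between 0.0128 and 0.0316, and at a pseudocount of 0.1 the calls on chromosomes 14 and X ended (adjusted p = 0.0647 and 0.0739).

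Of all 115491 tiles, 1572 had no overlap between the groups, which chance gives for 0.117% of tiles, and 616 rising and 66 falling tiles of the 947 called were among these. Of the sites tested, 0.77% of dense, 0.94% of intermediate and 0.4% of sparse ones rose, and 0.01%, 0.09% and 0.17% fell. Dense sites, at a mean of 7.7% in localized samples, left little room for falls of 20 points. Without localized sample 5 the calls fell to 204 tiles and 8341 sites. Falls numbered 74 tiles without CRPC sample 4, and limma in place of the quasi-binomial model called 1617 falling sites. The number of tiles also moved with the test, and was 92 at a pseudocount of 0.1. With one spread from all 3 groups it was 3524, of which 2653 rose and 871 fell. In tiles with at least 10 sites, 1117 rose and 41 fell. With the 6 shared numbers as a block, which do not pair these samples, limma called 0 tiles, so all 15 named calls ended, and 7685 tiles passed an unadjusted p below 0.05 and 20 points.

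**Figure D4:**
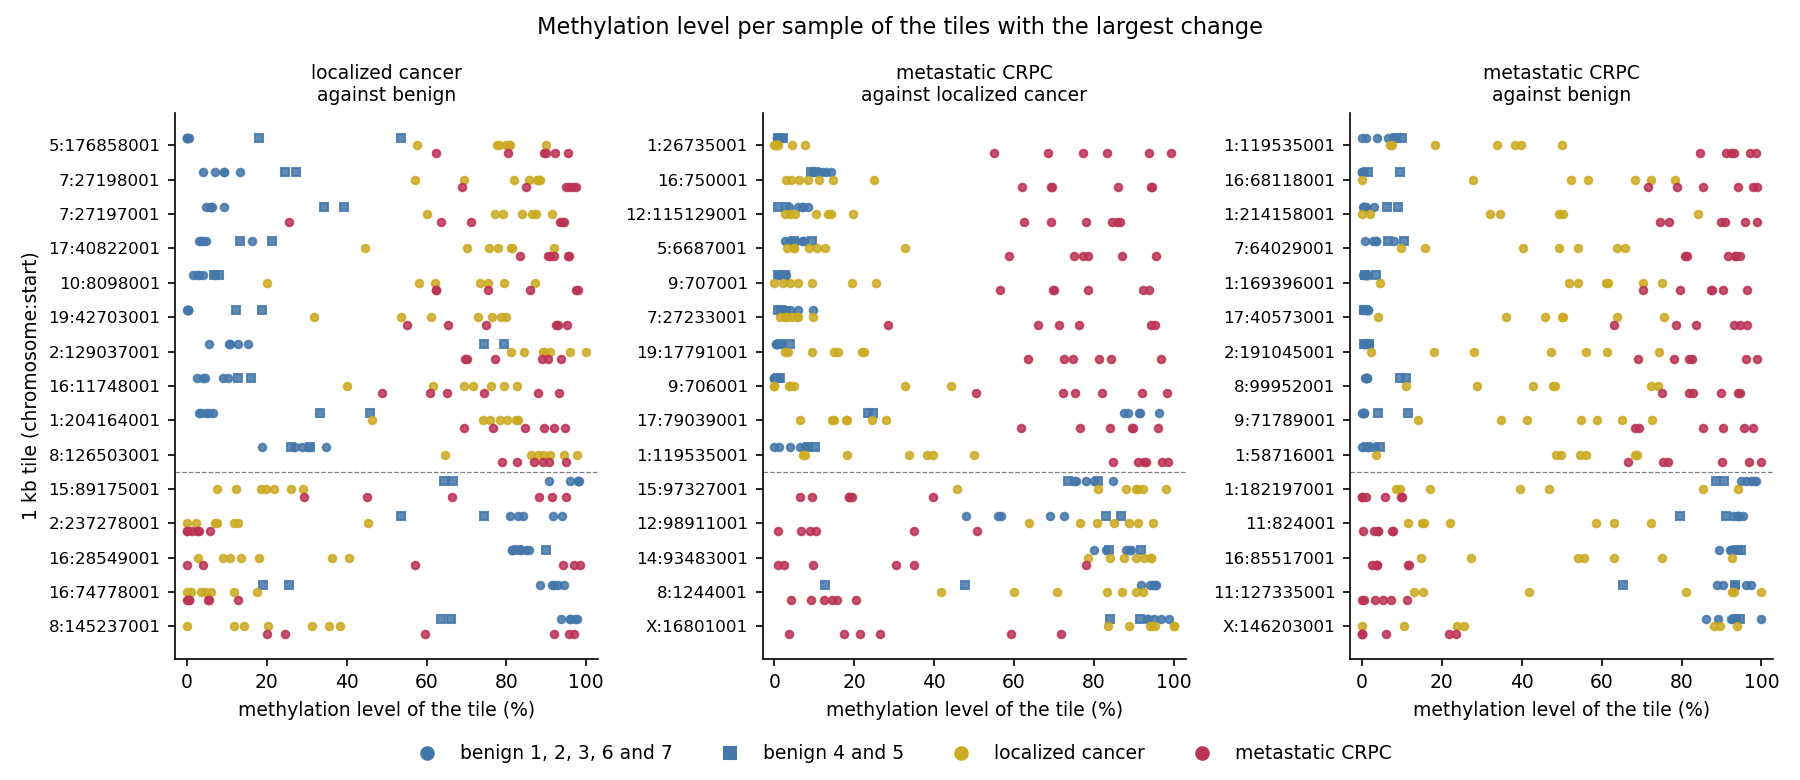
Methylation level in percent of each of the 20 samples at the 15 named tiles of each comparison, with tiles named by chromosome and start on the vertical axis; tiles above the dashed line rose and those below it fell. In each panel the samples of the compared groups do not overlap, and benign samples 4 and 5 (squares) lie between the other benign and the localized samples at several tiles of the first panel, such as chromosome 7 from 27197001 at 34.2% and 39.4%.

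Comparing CRPC with benign tissue asks what differs over the whole range of the series. In the window at chromosome 5, 140500001 to 141000000, 57 of 83 tiles rose, with benign samples 4 and 5 at a mean of 43.5% and 42.2% and the other 5 at 35.2% to 39.3%. At chromosome 15, 53000001 to 53500000, 15 of 17 tiles rose and the window mean went from 7.1% ± 3.2 (SD, n = 7) to 46.2% ± 7.7 (SD, n = 6), with benign samples 4 and 5 at 11% and 12.1% and the other 5 at 3.6% to 6.2%. At chromosome 12, 54000001 to 54500000, and chromosome 7, 27000001 to 27500000, 39 of 80 and 34 of 86 tiles rose, with means going from 17.9% to 48.1% and from 32.1% to 54.1%. Losses covered 21 of 23 tiles at chromosome 21, 11000001 to 11500000, where the mean went from 74.9% ± 0.7 (SD, n = 7) to 31.2% ± 8.2 (SD, n = 6). They covered 32 of 37 tiles at chromosome 8, 47000001 to 47500000, where it went from 81.4% ± 1.5 (SD, n = 7) to 43.0% ± 12.7 (SD, n = 6). In these loss windows benign samples 4 and 5 lay close to the other 5, at 75.8% and 74.2% on chromosome 21 and at 79.7% and 82.6% on chromosome 8.

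Among tiles without overlap of CRPC and benign samples, the one at chromosome 1, 119535001 to 119536000, rose most, by 87.5 points. Tiles at chromosome 16, 68118001 to 68119000, chromosome 1, 214158001 to 214159000, chromosome 7, 64029001 to 64030000, chromosome 1, 169396001 to 169397000, and chromosome 17, 40573001 to 40574000, rose by 86.2, 84.9, 84.2, 84.0 and 83.9 points from benign levels of 5.1% or less. In localized cancer these tiles stood at 50.9% ± 27.9, 36.0% ± 29.4, 42.7% ± 22.3, 54.1% ± 23.4 and 46.6% ± 22.7 (SD, n = 7). A tile of 50 sites at chromosome 8, 99952001 to 99953000, rose from 3.6% ± 4.5 (SD, n = 7) to 86.5% ± 7.7 (SD, n = 6), with benign samples 4 and 5 at 9.4% and 10.9%. The tiles at chromosome 2 from 191045001, chromosome 9 from 71789001 and chromosome 1 from 58716001 rose by 83.5, 82.1 and 82.0 points. Those at chromosomes 16 and 7, and at chromosome 1 from 58716001, 119535001 and 214158001, held 4 sites each.

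The largest fall among these tiles was at chromosome 1, 182197001 to 182198000, from 95% ± 3.9 (SD, n = 7) to 4.4% ± 4.8 (SD, n = 6), with 43.0% ± 35.1 (SD, n = 7) in localized cancer. The tiles at chromosome 11, 824001 to 825000, with 24 sites, and chromosome 16, 85517001 to 85518000, fell from 91.6% ± 5.4 and 92.6% ± 1.7 (SD, n = 7) to 4.5% ± 2.8 and 6.1% ± 4.3 (SD, n = 6). The tiles at chromosome 11, 127335001 to 127336000, and chromosome X, 146203001 to 146204000, fell by 84.6 and 84.1 points. Both of these, and the tile of chromosome 1, held 3 sites each. At all 15 tiles of this comparison the adjusted p by limma was 2.22e-05 or less and the call also held without either set of benign samples.

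**Figure D5:**
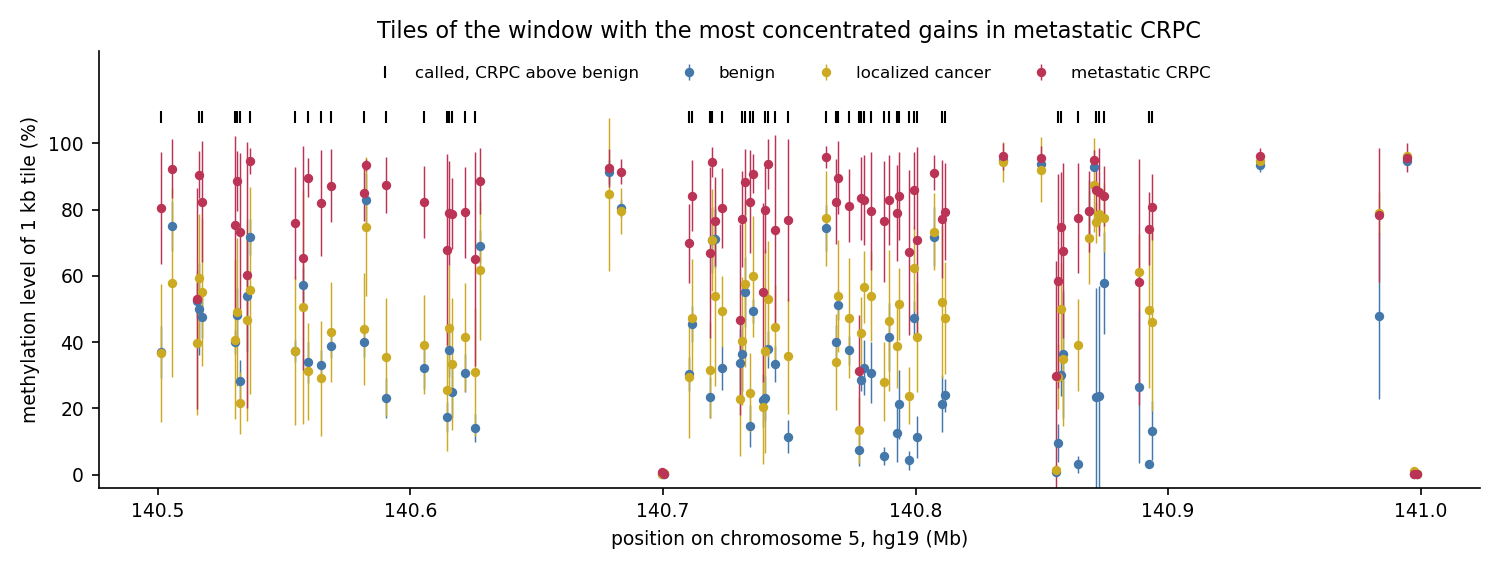
Group mean level in percent with SD of each 1 kb tile measured between 140500001 and 141000000 of chromosome 5 on hg19, in benign (n = 7), localized (n = 7) and CRPC samples (n = 6); ticks mark the 57 of 83 tiles called higher in CRPC than in benign tissue. Window means are 38.9% in benign, 47.4% in localized and 75.4% in CRPC samples.

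In counts, 9215 of 115491 tiles rose and 8417 fell between benign tissue and CRPC. Of all tiles, 8321 had no overlap of samples, which chance gives for 0.117% of tiles, and 4224 rising and 2810 falling called tiles were among these. Of 2199386 sites, 186973 rose, by a median of 50.5 points, and 111523 fell, with a median change of -43.3 points. Of the rising sites, 70.2% were below 20% in benign tissue, but a rise of 20 points or more favours low starts. Among the autosomal sites listed in all samples, 54.1% lay below 20% in benign samples on average. Rising sites made up 8.31% of dense, 11.8% of intermediate and 6.64% of sparse sites tested. Falling sites made up 0.47%, 3.36% and 8.27%, and the low level of dense sites in benign samples left little room for falls there. Among the 5219 called tiles with at least 10 sites, 4244 rose, so the balance moved from 52.3% to 81.3% of rises. Starting levels were not compared there either. Without benign samples 4 and 5, 297958 sites and 19735 tiles were called, and without the other 5, 53712 sites and 1279 tiles, of which 70.4% were gains. Against both benign sets separately, 6103 rising and 6476 falling tiles differed by 20 points or more.

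Many changes of localized cancer were also seen in CRPC, on tests that share the 7 benign samples. Of 2191017 sites tested in both comparisons against benign tissue, 75975 rose in both, which is 73.4% of those that rose in localized cancer, and 45599 fell in both, which is 49.7%. Independent lists of these sizes would share 8818 and 4648 sites, but lists measured against the same benign samples are not independent. The differences from benign correlated at 0.78 across sites, at 0.46 in simulated groups without any change measured against the same benign samples, and at 0.65 with the benign samples split into 3 and 4. Their covariance was 238.0 squared points against 13.4 in the simulated groups and 229.1 with the split. Any such split leaves samples of the set of 5 in both parts. Changes shared by the cancers are therefore not separated from the parting of the benign samples. Opposite directions were called at 27 and 17 sites, and the shared benign samples also work against opposite calls. Shared counts without the 5 benign samples could not be given, since localized cancer then had no calls, and they were not computed without benign samples 4 and 5.

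The tiles called in localized cancer were also looked up in CRPC, again against the same 7 benign samples and without a value for groups that do not change. Of the 6187 tiles that rose in localized cancer, 4712 were also called higher in CRPC than in benign tissue. Of the 6537 tiles that fell, 3253 were also called lower in CRPC. Against localized cancer, CRPC was called higher again at 212 of the risen tiles and lower at 16. At the fallen tiles it was called lower again at 11 and higher at 78. The median of CRPC minus localized was 7.5 points at risen and 3.8 at fallen tiles. The tiles were picked by the same localized samples, which favours a move back. The difference between gains and losses was not tested.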

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

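The tests on the sets of benign samples and on mitochondrial calls were chosen after the result was seen, some with their values already looked at. Samples were singled out here where 1 sample of a group lay far from the others, with its gap to the nearest one large against the range of the group. Chance gives about 1 in 20 groups such a sample. Among the named tiles it was seen in 12 of 90 groups, and among the measures taken per sample in 1 of 27. The 90 groups reuse the same samples at tiles picked for large differences, so their count cannot be weighed against chance.

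Benign sample 5 stood apart at 6 named tiles, each time in the direction of the cancers. The named tiles were picked for large differences, which left little room for the other direction. At chromosome 5, 176858001 to 176859000, it had a level of 53.5%, where benign sample 4 had 18.1% and the other 5 at most 0.4%. Its level was 9.6% at chromosome 16 from 68118001, where the other benign samples reached 1.4%, 3.5% at chromosome 1 from 169396001, where they reached 1.6%, and 11.4% at chromosome 9 from 71789001, where they reached 4.0%. It had 79.7% at chromosome 11 from 824001, where the others lay at 91.1% or above, and 65.3% at chromosome 11 from 127335001, where they lay at 88.9% or above.

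Localized sample 5 stood apart at 4 named tiles, each time in the direction of the benign samples, which the choice of these tiles also favours. Its level was 57.6% at chromosome 5 from 176858001, 46.4% at chromosome 1 from 204164001 and 64.7% at chromosome 8 from 126503001, below the other localized samples. It was 45.3% at chromosome 2 from 237278001, above them. Localized sample 2 had 32.6% at chromosome 5 from 6687001, above the other localized samples, and 45.6% at chromosome 15 from 97327001, below them.

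Mitochondrial DNA lay outside the comparisons. CRPC sample 3 had 0.251% methylated calls there, apart from the other CRPC samples and above the highest benign sample at 0.135%, as did 3 of 13 cancer samples. CRPC sample 2 had mitochondrial calls at 5404.9 RPM, which scales them to a common total of calls, above the highest benign sample at 3337.3, as did 5 of 13 cancer samples. Localized cancers had 2565.63 RPM ± 1154.94 (SD, n = 7) against 1086.53 ± 1209.67 (SD, n = 7) in benign samples (exact permutation p = 0.0449, not adjusted). Much of this difference goes with the split of the benign samples. Benign samples 1, 2, 3, 6 and 7 had 146.6 to 569.8 RPM. Benign samples 4 and 5 had 2230.8 and 3337.3 RPM, within the localized range of 1013.1 to 3855.0 RPM. Each localized sample also lay above the benign sample of its own number, by little for number 5 (3374.0 against 3337.3 RPM), and the pairs were not tested.

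For the first pattern weighed, the parting of the benign samples into 1, 2, 3, 6 and 7 against 4 and 5, a library from another donor is argued against, since each benign sample matched the localized sample of its own number at candidate variant sites, with a lowest correlation of 0.119 against 0.013 at most between different numbers. Cancer DNA mixed into both samples was tested first and cannot be told apart: of 556 tiles below 10% in the other 5 benign samples and above 60% in every CRPC sample, 7.6% were below 10% in both (Wilson interval 5.6% to 10.1%), with 10% set as the bound. It was then tested per sample with the localized sample of the same donor. For benign sample 4, 28.9% of 1386 tiles stayed below 10%. This argues against a share of cancer DNA large enough for differences of 40 points between the sets, but not against a small share. For benign sample 5 it cannot be told apart, since 0.0% of 308 tiles stayed below 10% and localized sample 5 itself was only 3.7% of the way to CRPC. Another mix of cell types in one of the sets may be the cause and stays open: at 73.7% of the 4900 tiles that part the sets, just under the 75% set for it, at least 5 of 7 localized samples lay nearer to benign samples 4 and 5. Doubt therefore remains whether the set of 5 holds the same tissue as benign samples 4 and 5 and whether localized sample 5, nearer to these at 94.7% of the tiles, is mostly cancer, and with it what each difference from benign tissue means.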

How the results depend on the processing

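The fits without single samples or without a set of benign samples were chosen after the data were seen, and the other alternatives before. For the mean level of dense sites, CRPC kept direction and call against localized cancer and against benign under all 5 other settings. The same held in every fit without samples. The spread also kept direction and call in all 3 comparisons, except where only benign samples 4 and 5 were left. Both samples then share their only pair, so no call of the spread is judged there. Its differences kept their direction, at 5.42 points for localized cancer and 8.18 for CRPC. Calls for mean levels are judged here by the unadjusted exact p. Where a value moved and no reason is given, the cause was not tested.

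Coverage minimums leave fewer sites to test. At 30 reads, 133314 sites were called for localized against benign, 2867 for CRPC against localized and 86876 for CRPC against benign, and at 20 reads the last 2 counts were 8604 and 165747. At 20 reads 6484, 548 and 8779 tiles were called in the same order, and with at least 10 sites per tile 3195 for localized and 5219 for CRPC against benign, of which 68% and 81.3% were rises in place of 48.6% and 52.3%. For CRPC against localized cancer, 70514 sites and 3524 tiles were called with a spread from all 3 groups, and the tiles numbered 92 and 1608 at pseudocounts of 0.1 and 5, 2063 by the quasi-binomial model, 1446 on unweighted levels and 1431 in tiles of 500 bp. This count of tiles therefore depends on the test, while the counts of tiles of the other 2 comparisons moved by over 1.5 times only at a coverage minimum of 20, with at least 10 sites or without the 5 benign samples.

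With the replicate block for localized against benign samples, 369212 of 1936347 sites were called in place of 227317 of 2550581. The share of rises among them went from 54.9% to 46.0%. The pairing and the sites tested changed together here. The block called 11555 tiles, of which 11048 were among the 12724 called without it. It changed no call of mean level, of spread or of a named tile in that comparison. CRPC samples share only numbers with the others, with same-number correlations as low as -0.017 and -0.018, and 0 and 3 of 6 CRPC samples matched their own number best among localized and benign samples. With these numbers as a block, 12396 sites and 0 tiles (limma, 7685 at an unadjusted p below 0.05 and 20 points, no other tool run) were called against localized cancer and 329719 sites and 15151 tiles against benign. The differences at intermediate sites were then 3.97 (exact p = 0.188) and 4.55 points (exact p = 0.0625), and that of sparse sites against localized cancer reversed to -0.13.

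Without benign samples 1, 2, 3, 6 and 7, which leaves 2 benign samples, localized against benign gave 0 sites (quasi-binomial, 120378 at an unadjusted p below 0.05 and 20 points, 0 by limma) and 0 tiles (limma, 4988 and 6 by the quasi-binomial model), and CRPC against benign 53712 sites and 1279 tiles. The rise of dense sites in localized cancer was then 1.52 points (exact p = 0.0556) and that of intermediate sites in CRPC 4.81 (exact p = 0.214). Without localized sample 5 or CRPC sample 4, CRPC against localized cancer ranged from 8341 to 14750 sites and from 204 to 820 tiles, the lower values being without localized sample 5. Without localized sample 5, 270903 sites and 15620 tiles were called against benign, sparse sites differed by -4.82 points (exact p = 0.0449) and intermediate sites of CRPC and localized cancer by 4.09 (exact p = 0.0714). Without CRPC sample 4 the last difference was 4.5, and 244070 sites and 17305 tiles were called for CRPC against benign.

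Over all sites of each sample, localized cancer differed from benign by 1.68 points (exact p = 0.241), a reversal, and by 1.87 at intermediate sites (exact p = 0.0245), while CRPC differed by 4.97 (exact p = 0.0035) and, reversed, by 0.19 at sparse sites (exact p = 0.914). Weighted by coverage, the differences were 2.09 at intermediate sites for localized against benign (exact p = 0.0122), 3.56 and 3.43 over all sites for CRPC against localized and benign (exact p = 0.0303 and 0.0204) and, reversed, -0.58 at sparse sites for CRPC against localized (exact p = 0.85). At a coverage minimum of 20, intermediate sites gave -0.09 for localized against benign, reversed (exact p = 0.897), 3.45 for CRPC against localized (exact p = 0.0717) and 3.35 against benign (exact p = 0.0513).

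The named tiles kept direction and call in 114 of 114 cases set beforehand for localized against benign, 117 of 117 for CRPC against benign and 98 of 117 for CRPC against localized. In the last, 15 calls ended with the block and 4 at a pseudocount of 0.1. The setting of 10 points reused the same test and could end no call, which covers 15 cases in each comparison. For localized against benign, only 3 tiles could be looked up at a coverage minimum of 20 and 6 with at least 10 sites. With the block rises were still 64.1 to 77.2 points and the falls -59.8 to -63.9 points. Without the 5 benign samples all 15 calls of localized against benign ended. The differences there stayed at 58.7 points at chromosome 8 from 126503001, 57.8 at chromosome 10 from 8098001 and -67.8 at chromosome 16 from 28549001, but came to 13.2 at chromosome 2 from 129037001 and -15.9 at chromosome 16 from 74778001. Calls also ended without localized sample 5 at 1 of 15 tiles of CRPC against localized. Promoter windows and gene lists were not run, without an hg19 annotation here. Depth limits CRPC sample 4 most (median of 19 reads).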

Other observations

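The windows and the tests by other splits of the samples for tiles, and by splits that part all pairs, were chosen after the result was seen. The tests of dilution, of the spread and of the splits for sites were set before their results.

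Further stretches gained methylation from benign tissue to CRPC. At chromosome 12, 114500001 to 115000000, 20 of 28 tiles rose, and the window mean went from 21.8% ± 2.1 (SD, n = 7) through 30% ± 9.4 (SD, n = 7) in localized cancer to 55.7% ± 14.7 (SD, n = 6). At chromosome 3, 147000001 to 147500000, 19 of 26 tiles rose, with means of 12.7% ± 2.6, 17.5% ± 10.1 and 42.6% ± 16.9 (SD, n = 7, 7 and 6). At chromosome 15, 68000001 to 68500000, 8 of 29 tiles rose from localized cancer to CRPC, from 32.6% ± 3.7 (SD, n = 7) to 48.4% ± 5.8 (SD, n = 6), and all benign samples lay between 24.1% and 25.6%. At chromosome 14, 57000001 to 57500000, 12 of 25 tiles rose already in localized cancer, with means of 37.1% ± 2.3, 51.7% ± 6.8 and 75.5% ± 13 (SD, n = 7, 7 and 6).

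Losses in CRPC covered most tiles of windows that were even in all benign samples. At chromosome 18, 73500001 to 74000000, 19 of 22 tiles fell, with means of 79.4% ± 1.4, 49.4% ± 24.7 and 37.8% ± 10.1 (SD, n = 7, 7 and 6). At chromosome 12, 34000001 to 34500000, 29 of 46 tiles fell, with means of 74.0% ± 1.0, 53.0% ± 19 and 45.1% ± 8.1, and at chromosome 8, 2000001 to 2500000, 23 of 34 fell, with means of 81.4% ± 0.8, 59.1% ± 21 and 45.2% ± 8.2 (SD, n = 7, 7 and 6). In these 3 windows benign samples 4 and 5 lay at 78.4% and 77.9%, 74.3% and 72.9%, and 82.1% and 81.4%, so the split of the benign samples was small there. The SD of the localized samples exceeded that of the CRPC samples in all 3.

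The second pattern weighed is that localized samples lay between benign and CRPC samples where these differ. A lower share of cancer DNA in the localized samples, and nothing else, would put each sample equally far along at gained and at lost tiles. This is argued against, since in 5 of 7 localized samples the medians differed by more than 10 points with an interval that leaves out 0. Localized samples 2 and 3 were 55.2% and 43.1% of the way at 42 gained tiles and 18.4% and 9.7% at 48 lost tiles, while samples 4, 6 and 7 were at 70.2%, 54.4% and 40.4% for gains and at 97.9%, 94.1% and 82.8% for losses. Dilution in addition to another difference stays open, as for sample 5 at 3.7% and -1.4%, and no biological explanation was tested.

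The third pattern weighed is the larger spread among CRPC samples than among localized cancers. Lower depth of the CRPC libraries is argued against, since with every site thinned to 10 reads the difference was still 2.37 points (exact permutation p = 0.000583, the smallest possible). Sequence variants of the donors are argued against as the whole of it, since without candidate variant sites the difference was 2.58 points (exact permutation p = 0.000583). Spread values of a group share pairs of samples, so both p values may be too small. Different tissue sites or cell mixes of the metastases were not tested, and neither was any biological explanation.

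For each comparison, 100 splits of its samples into groups of the same sizes, the real one included, were compared, on every 20th site and on all tiles. In all 6 cases at most 2 of the 100 splits reached the real count, the real one included. This argues against chance but cannot exclude it. For sites of localized against benign, 1 split reached the real count of 11394, with 4298 as the highest other, and for CRPC against benign 1 split reached 14923, with 6338 as the highest other. For sites of CRPC against localized cancer, 2 splits reached 905 and the highest other gave 1288: it set localized samples 4 and 6 with CRPC samples 1, 2, 3 and 4, a structure that crosses the groups. For tiles the real counts were 12724, 947 and 17632, reached by 2, 1 and 1 splits, with highest others of 14534, 1 and 1910. The split with 14534 tiles exchanged benign sample 5 and localized sample 5. Among the 64 splits that part all 7 pairs of localized and benign samples, 2 reached the real counts of 11394 sites and 12724 tiles, the highest others of 12155 and 14534 both came from that same exchange, and the median of the others was 0.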
